A study of Mus musculus with 6 samples.

How the data were processed

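Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled in hematopoietic stem cells from mouse bone marrow with CUT&RUN, in which an antibody directs a micrococcal nuclease fusion to the mark and the released DNA fragments are sequenced. The labels describe 3 libraries from wild-type mice and 3 from mice deficient in Ppp2ca, the gene of the alpha catalytic subunit of protein phosphatase 2A (PP2A). Per the series text each group came from 3 mice, and each library was taken as 1 mouse, although no label carries an animal number. The part of Ppp2ca that was deleted is not given in the sources used here.

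Per the submitters' processing notes, Trimmomatic, BWA, MACS2, deepTools, HOMER and ChIPseeker were used with the GRCm38/mm10 build; versions, parameters and the use of a control library are not given in the sources used here. The deposited files are narrowPeak lists, and the peak names inside them number 1 list per library, so replicates were not pooled. In these lists the deposited ratio is the fold enrichment at the summit over the caller's background. The deposited −log10 p-value and −log10 q-value belong to the same summit, and the deposited score was the integer part of 10 times the −log10 p-value in at least 99.9% of the peaks of 5 libraries. The lowest −log10 p-value lay between 2.005 and 2.006 in all 6 lists, as a p threshold of 0.01 would leave, and most wild-type peaks lay above a q-value of 0.05. Fold and q-values are the authors', depend on the depth of each library, and were used to describe, rank or filter peaks within a list. Heights were not tested between lists, and folds printed for both genotypes are descriptive. Numbers of peaks passing a q threshold were compared between genotypes, so they carry that dependence on depth.

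Read totals are not in the lists, so depth was approached from the peaks themselves. The fold is (pileup + 1) divided by (background + 1), and the p-value is a Poisson tail of the pileup, so the pair can be solved for both. Whole-number pileups came out for at least 99.96% of the peaks of each library with −log10 p-value under 15, at a tolerance of 0.002. The commonest background is the genome-wide number of fragments per 200 bp. It was 0.499, 0.584 and 0.498 in wild-type replicates 1 to 3 and 0.738, 0.465 and 0.827 in knockout replicates 1 to 3. The value is a proxy for usable depth; the median summit pileup of 5 fragments in each wild-type library shows how few fragments a typical peak rests on.

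The only reference used was a RefSeq gene table of GRCm38.p6, the same build, with the start and end of 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table holds no strand, so a transcription start could not be told from the other end of a gene. Promoter results were planned; in their place a gene was called marked where a peak overlapped the 1000 bp on either side of either gene end. Exons, introns and UTRs were not analysed here.

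Regions were the union of the peaks of all 6 libraries, merged where they overlapped by at least 1 bp. A knockout-only region or gene end had a peak in all 3 knockout and no wild-type library, and a wild-type-only one the reverse. Numbers per library were compared with a two-sided exact permutation test over the 20 assignments of 3 and 3 libraries, whose smallest p is 0.1, so this test could make no call at 0.05. Counts of regions and genes were set beside the other 9 of the 10 splits of the libraries. The similarity of lists was the Jaccard index in base pairs. For 26 gene lists fixed before the data were examined, with 680 entries of which 677 matched by symbol, 1 by synonym and 2 not at all, membership was tested in both directions. Fisher's exact test was used at gene ends, against the 11087 genes marked in any library. For nearby regions, each region was assigned only to its nearest protein-coding gene end, if within 50 kb. The exclusive share of a list's regions was set against 10000 random lists matched on regions per gene. Each family of 52 tests was adjusted by Benjamini-Hochberg. Genes are not independent replicates, so list tests describe these 6 libraries.

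Named genes followed a rule fixed before the data were examined: Ppp2ca, the 10 knockout-only and 10 wild-type-only genes with the best rank in their weakest library, up to 4 exclusive members of each list, and otherwise 2 members marked in all 6 libraries. Gene windows that overlap are named together. Some genes that the rule selects are not reported here. Alternatives were stricter −log10 q-values of 5 and 10, equal numbers of peaks per library, other overlap rules, windows, distances and backgrounds, chromosomes 1 to 19 alone, a replicate block, and leaving out each library. Peaks with a q-value of at most 0.05, random lists matched on the rank of genes in the knockout lists, and leave-one-out runs of the gene lists were added after the data had been seen.

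The procedure was tested on simulated data. With the 104459 regions as a frame, 200 of 200 planted knockout-only regions were recovered. These were set present in every knockout and no wild-type list, so their recovery checks the counting alone, not the sensitivity at this depth. With each region at its own mean rate of detection, scaled to the list lengths and with no group effect, 1422 other regions were knockout-only and 100 wild-type-only. In the frame of 21887 genes, a planted list of 27 genes reached an adjusted p of 0.978 with 6 knockout-only members, 0.0515 with 8 and 0.00142 with 10, and 6 of 100 lists without an effect had p under 0.05 in Fisher's exact test. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1, the last as a check of the merged regions.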

Results

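H3K27ac was mapped by CUT&RUN in hematopoietic stem cells from the bone marrow of wild-type and Ppp2ca-deficient mice, with 3 libraries per genotype, to ask which sites of the mark depend on Ppp2ca. The lists held 22066, 29945 and 21917 peaks in wild-type replicates 1 to 3 and 50453, 34016 and 35629 in knockout replicates 1 to 3. The genome background recovered from the lists was 0.527 ± 0.0494 fragments per 200 bp (SD, n = 3) in the wild type and 0.677 ± 0.189 (SD, n = 3) in the knockout, with overlapping ranges (two-sided exact permutation p = 0.4).

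Ppp2ca itself (chromosome 11, 52098824 to 52122749, GRCm38) carried a peak over its low-coordinate end in all 6 libraries. The peak was 786 to 1232 bp wide in the wild-type libraries and 1566 to 1681 bp wide in the knockout libraries. Its fold over background, as the authors' caller gave it, was 4.08 to 6.20 in the wild type and 5.83 to 6.66 in the knockout. Peaks of 200 bp inside the gene were listed in knockout replicate 1 (52115711 to 52115910) and knockout replicate 2 (52112968 to 52113167) and in no other library. Because the labels do not say which part of the gene was removed, the peak at its end does not check the genotype.

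**Figure D1:**
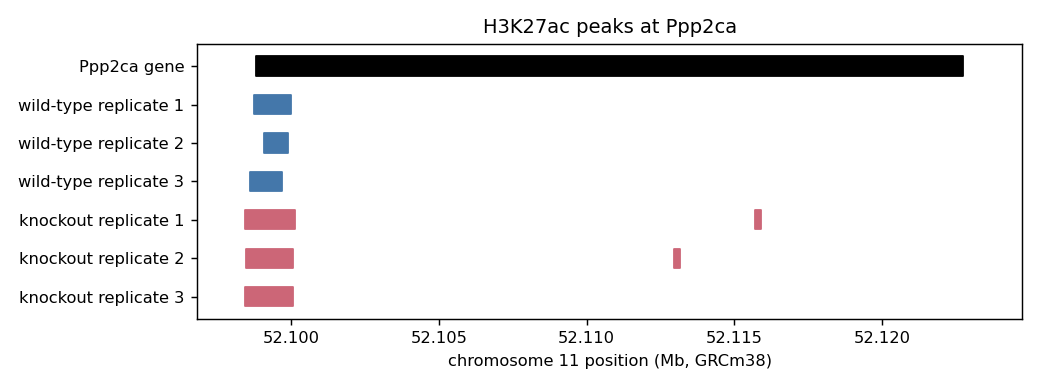
Position on chromosome 11 in Mb (GRCm38) against library, with the Ppp2ca gene in black, wild-type peaks in blue and knockout peaks in red. All 6 libraries have a peak at the low-coordinate end, and 2 knockout libraries have a 200 bp peak inside the gene.

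The first comparison asked how much of the genome carried called H3K27ac in each genotype. The knockout lists were longer, with 40033 ± 9060 peaks (SD, n = 3) against 24643 ± 4593 (SD, n = 3), a ratio of 1.62. They covered 18.9 ± 4.12 Mb (SD, n = 3) against 8.04 ± 1.35 Mb (SD, n = 3), a ratio of 2.36, and the median peak width was 336 bp against 230.3 bp. Every knockout library exceeded every wild-type library in number and coverage, and each two-sided exact permutation p was 0.1, the smallest the design allows. Peaks with a q-value of at most 0.05, a threshold added after the data had been seen, numbered 20664 ± 4017 (SD, n = 3) in the knockout and 4005 ± 598 (SD, n = 3) in the wild type, a ratio of 5.16, with exact permutation p = 0.1. They made up 52.6% of the knockout lists and 16.3% of the wild-type lists.

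**Figure D2:**
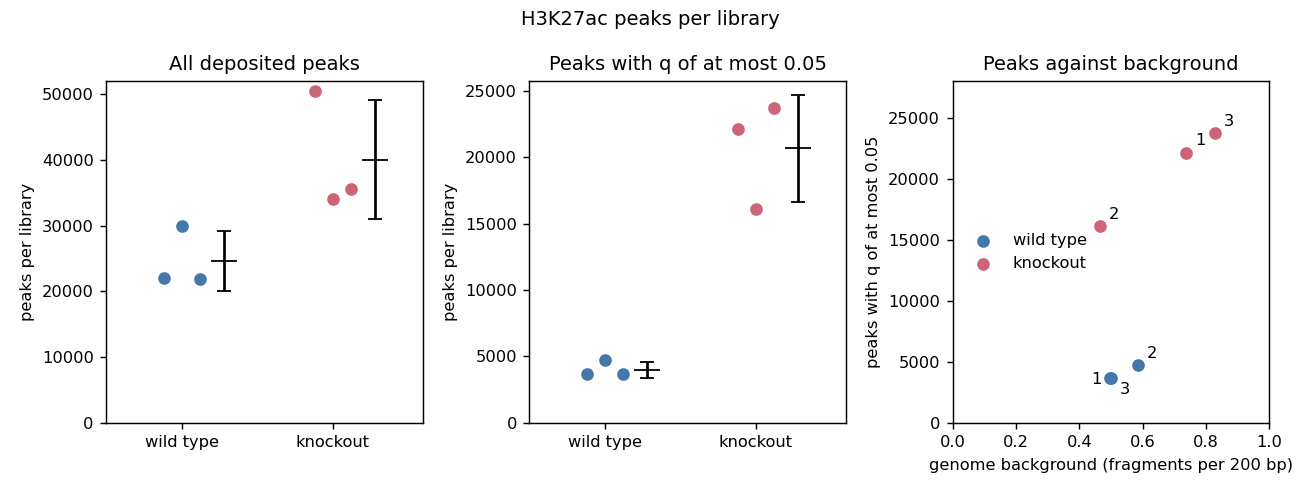
Left and middle, all deposited peaks and peaks with a q-value of at most 0.05, in peaks per library, with points for libraries and bars for the mean ± SD of 3. Right, the stricter peaks against genome background in fragments per 200 bp, with replicate numbers. Knockout replicate 2 has the lowest background, 0.465, and 16120 stricter peaks, while the wild-type libraries have 3652 to 4695.

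Most of the strongest regions were shared between the genotypes. The 50 strongest peaks of each library fell into 49 or 50 regions, of which 46 were among the strongest of all 6 libraries. Of these 50 peaks, 21 to 24 lay on chromosome 9, 3 lay off the main chromosomes and 40 to 42 lay over 10 kb from any protein-coding gene end. By contrast, 49.7% of wild-type and 38.6% of knockout peaks with a q-value of at most 0.05 lay within 1000 bp of a gene end. Regions prone to artefact were not filtered out here, and whether these 50 peaks reflect H3K27ac was not tested. Knockout libraries shared more of their peak sequence with each other, at a mean Jaccard index of 0.330 (range 0.292 to 0.358), than wild-type libraries did, at 0.157 (range 0.151 to 0.164). Pairs of different genotype had a mean of 0.174. The mean within genotypes, carried by the knockout pairs when all peaks were used, exceeded that between genotypes by 0.0691, the largest of the 10 splits (exact share 0.1). With peaks of a q-value of at most 0.05 the means were 0.398 within the knockout, 0.240 within the wild type and 0.132 between genotypes. Measured as the share of the shorter list that overlapped the longer, the difference was -0.0145.

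The next comparison sought regions marked in a single genotype. The 2824 knockout-only regions were led by chromosome 11 from 3201609 to 3202654, where Gm51877, Eif4enif1 and Sfi1 lie, with a fold of 5.10 to 6.17 over background in the knockout libraries. Next came chromosome 7 from 27978523 to 27979610 at an end of Zfp780b, chromosome 12 from 72085431 to 72086814 over the adjacent ends of L3hypdh and Jkamp, chromosome 11 from 79339063 to 79339836 at Nf1, the gene of the Ras inhibitor neurofibromin, and chromosome 13 from 38658358 to 38659252 at Eef1e1. All 5 had a peak with a q-value of at most 0.05 in every knockout library. Only 33 regions were wild-type-only. The best ranked lay inside Pisd (chromosome 5, 32737387 to 32738281), 32016 bp from an end of Podxl (chromosome 6, 31595953 to 31596357), inside Sfi1 (chromosome 11, 3168717 to 3169072), near Mid1 (chromosome X, 170005551 to 170005927) and near Gdi2 (chromosome 13, 3519977 to 3520336). The leading knockout-only region and 1 of these thus lay in the same Sfi1 neighbourhood.

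Of 104459 regions, 73.5% had a peak in 1 library only and 5501 had one in all 6. The highest count of exclusive regions in another split of the libraries was 503, and 10 splits cannot give a share under 0.1. A gene end lay within 1000 bp of 33.1% of knockout-only regions and of 57.2% of regions found in all 6 libraries. The knockout-only regions were also narrower, with a median width of 807 bp against 1502 bp. Merging the peaks of 6 rather than 3 libraries widens a region by itself, so the widths and gene-end shares are not like for like. Knockout-only regions ranked lower, at a median percentile of 63.2 against 16.4 in their weakest knockout library, where 0 is best. Regions with a peak in all 3 knockout libraries numbered 14994. When these were put into 10 rank groups by their peaks in the knockout lists, 97.0% ± 0.40 (SD, n = 3 wild-type libraries) of the strongest group also had a peak in a given wild-type library, falling to 24.8% ± 1.88 (SD, n = 3) in the weakest group. The share without any wild-type peak went from 0.133% to 49.3% from the strongest to the weakest group. Cutting every list to the 21917 best peaks left 1386 knockout-only and 66 wild-type-only regions, and a q-value of at most 0.05 gave 4714 and 2. Requiring only the other 2 knockout libraries gave 4302 knockout-only regions without knockout replicate 1, 5641 without replicate 2 and 4480 without replicate 3.

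**Figure D3:**
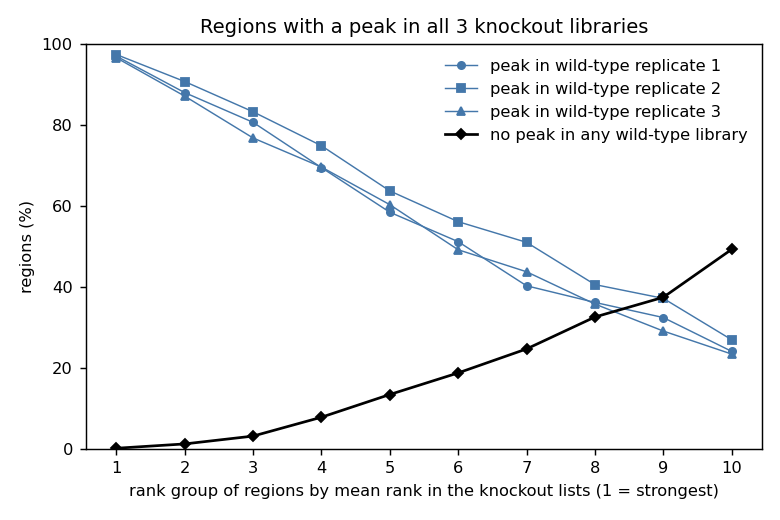
Regions with a peak in all 3 knockout libraries, in 10 groups by mean rank in the knockout lists (1 is strongest), against the percentage with a peak in each wild-type library (blue) or in none (black). Detection falls from 97.0% to 24.8% on average, and the share in no wild-type library goes from 0.133% to 49.3%.

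At the level of genes, 898 protein-coding genes had a peak at a gene end in all 3 knockout and no wild-type library. The best ranked were Gm51877 and Eif4enif1, which share a window with Sfi1, then Naif1 (with Slc25a25), Zfp780b, L3hypdh (with Gpr135 and Jkamp) and Jkamp (with Ccdc175 and L3hypdh), Ttbk2 (with Cdan1), Nf1, Eef1e1 and the histone gene H1f6 (with H4c3). The folds over background of these 10 genes in the knockout libraries ranged from 4.98 at Naif1 to 8.70 at L3hypdh and Jkamp. The absence in the wild type concerned the gene-end windows alone. At 73 (8.13%) of the 898 genes the merged region under the knockout peaks also held a wild-type peak outside the window, as at Naif1 and H1f6 in 3 wild-type libraries and at Ttbk2 in 1. Nf1 had peaks elsewhere in the gene in all 3 wild-type libraries. Zfp985 and the chemokine receptor-like gene Ccr1l1 were the 2 wild-type-only genes. At Ccr1l1 all 3 knockout libraries had a peak in the same merged region, outside the window, and neither gene had a gene-end peak with a q-value of at most 0.05 in any library.

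Gene ends were marked at 9199 ± 516 genes (SD, n = 3) in the knockout and 6028 ± 444 (SD, n = 3) in the wild type, a ratio of 1.53 with exact permutation p = 0.1, and 3713 genes were marked in all 6 libraries. Of the 898 genes, 459 (51.1%) had a peak with a q-value of at most 0.05 in all 3 knockout libraries. The highest count in another split was 90. With peaks of a q-value of at most 0.05 the knockout-only genes numbered 2720 and the wild-type-only genes 0, and without wild-type replicate 2 the knockout-only genes numbered 1563.

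Gene groups fixed before the data were examined were then followed through the libraries. Interferon response genes were marked at 25 ± 2 of 28 members (SD, n = 3) in the knockout and 14 ± 1 (SD, n = 3) in the wild type. Isg15, an interferon-induced ubiquitin-like modifier (window shared with Agrn), Xaf1 (with Fbxo39), Oasl2 and Oas1a were among the 5 knockout-only members (Oas1a was named after its values were seen), with folds of 4.23 to 5.22 at Isg15. Histone acetylation enzymes and readers were marked at 23.3 ± 0.577 of 30 members in the knockout and 13.3 ± 2.08 in the wild type (SD, n = 3 each). Their 5 knockout-only members included the acetyltransferases Kat6a and Kat2a (with Dhx58 and Hspb9) and the deacetylases Hdac8 and Hdac7 (with Slc48a1), and the deacetylase Sirt1, named after its values were seen. Kat6a and Hdac7 had peaks elsewhere in the gene in all 3 wild-type libraries. In 2 wild-type libraries a peak lay in the same merged region as Kat2a, outside its window. A gene-end peak with a q-value of at most 0.05 occurred in 2 knockout libraries at Oasl2 and Kat2a and in 1 at Hdac7. At Kat6a, Hdac8, Kat2a and Hdac7 the best-ranked peak of 1 knockout library overlapped neither of the others.

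Among signalling groups, PI3K-AKT-mTOR genes were marked at 25 ± 1 of 26 members in the knockout and 17.3 ± 0.577 in the wild type (SD, n = 3 each). Rptor, the scaffold of mTOR complex mTORC1, and Foxo4 (with Gm614) were among the 3 knockout-only members. PP2A subunits and regulators were marked at 22 ± 1 of 28 against 16.7 ± 1.15 members (SD, n = 3 each), with the regulatory subunit gene Ppp2r5d (with Mea1) and the striatin gene Strn knockout-only. For the MAPK pathway the knockout-only genes were Mapk8 and Sos1, for the Wnt pathway Dvl3 (with Ap2m1) and Lrp6, and for the immediate early genes Atf3. For p53 and apoptosis genes, marked at 21.7 ± 2.08 of 28 against 14.7 ± 2.08 members (SD, n = 3 each), they were Gadd45a and the BH3-only genes Pmaip1 and Bid (with Bcl2l13). Traf6, Chuk (with Cwf19l1) and Il6 were the knockout-only NF-kB and inflammation genes. Fanca (DNA repair), Ctsb (with Fdft1) and Map1lc3a (with Pigu; both in autophagy and lysosome) completed these groups. A gene-end peak with a q-value of at most 0.05 occurred in only 1 knockout library at Sos1, Lrp6, Atf3 and Il6. It occurred in 2 knockout libraries at Foxo4, Mapk8, Dvl3, Bid and Chuk. At Atf3 and Il6 the best-ranked peaks of the 3 knockout libraries did not overlap one another. At Foxo4, Sos1, Lrp6, Pmaip1 and Bid the best-ranked peak of 1 knockout library overlapped neither of the others. Elsewhere in the gene, Rptor, Mapk8, Lrp6, Fanca and Ctsb had peaks in all 3 wild-type libraries. The merged region held a wild-type peak outside the window in 2 libraries at Ctsb and 1 at Gadd45a. In knockout against wild-type libraries these lists were marked at means of 20.3 and 13 of 26 members (MAPK), 9.67 and 3.67 of 30 (Wnt), 17.3 and 12.3 of 22 (immediate early genes) and 23.3 and 16.7 of 30 (NF-kB). The means were 22.7 and 14.3 of 26 for DNA repair and 21 and 15.7 of 22 for autophagy and lysosome.

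Stem cell and lineage groups followed. HSC identity genes were marked at 8 ± 3 of 30 members in the knockout and 7.33 ± 2.31 in the wild type (SD, n = 3 each; exact permutation p = 0.9), with no exclusive member. With peaks of a q-value of at most 0.05 the same windows gave 6 ± 1.73 against 1.33 ± 0.577 members (SD, n = 3 each; exact permutation p = 0.1). Etv6 (with Gm46977) and Lyl1 (with Nfix and Trmt1) were marked in all 6 libraries. With a q-value of at most 0.05 Etv6 was marked in 3 knockout and 1 wild-type libraries, and Lyl1 in 2 and 0. HSC quiescence genes were marked at 13 ± 1 of 19 against 8.67 ± 1.53 members (SD, n = 3 each). Erythroid genes were marked at 14 ± 1 of 23 against 8 ± 3.46 members and myeloid genes at 16.3 ± 1.15 of 28 against 10.7 ± 2.08 (SD, n = 3 each). The erythroid regulator Klf1 was marked in all 6 libraries, and Ly6c2 was the knockout-only myeloid gene. Klf1 had a gene-end peak with a q-value of at most 0.05 in 3 knockout and 0 wild-type libraries. Its best-ranked peaks did not all overlap, as at 84901229 to 84901428 in wild-type replicate 2 and 84902957 to 84903291 in knockout replicate 2. Megakaryocyte genes were marked at a mean of 7.33 members in both genotypes, with Gp1ba (with Slc25a11) and Itga2b in all 6 libraries. With a q-value of at most 0.05 they were marked at 7, 1 and 4 members in knockout replicates 1 to 3 and at 1, 2 and 0 in the wild type (exact permutation p = 0.3). At that threshold Gp1ba was marked in 2 knockout and 0 wild-type libraries, and Itga2b in 2 of each genotype. Lymphoid progenitor and B cell genes were marked at 10, 3 and 4 of 26 members in the knockout and 3, 2 and 6 in the wild type (exact permutation p = 0.6), so the higher knockout mean rested on replicate 1, and Tcf3 was marked in all 6 libraries. Few members were marked of the lists for T and NK cells (5 against 3.33 of 27), mast cells (2.67 against 1.33 of 16), endothelium and stroma (4 against 1.33 of 22) and other organs (1 in each genotype, of 32). Those lists gave Cd5, Kdr and Vil1 (with Usp37) as their knockout-only members. Each of these 3 genes had a gene-end peak with a q-value of at most 0.05 in only 1 knockout library.

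Housekeeping genes, a control list, were marked at 27.7 ± 1.53 of 30 members in the knockout and 24 ± 2.65 in the wild type (SD, n = 3 each), with Actg1 and B2m in all 6 libraries. At Actg1 a gene-end peak with a q-value of at most 0.05 occurred in 3 knockout and 0 wild-type libraries. Cell cycle genes (26 ± 1 against 21 ± 1 of 30), oxidative phosphorylation genes (24.3 ± 0.577 against 19.7 ± 0.577 of 28) and polycomb and trithorax genes (19.3 ± 0.577 against 15.3 ± 1.53 of 25; SD, n = 3 throughout) had no knockout-only member. In these lists Aurka (with Cstf1 and Fam210b), Aurkb, Atp5a1 (with Haus1), Atp5b (with Baz2a), Ash1l (with Dap3) and Dot1l (with Plekhj1) were marked in all 6 libraries. Glycolysis and hypoxia genes were marked at 13 ± 2.65 against 7 ± 1 of 24 members (SD, n = 3 each), with none exclusive and none in all 6. For 18 of the 26 lists every knockout library had more marked members than every wild-type library and for 0 lists fewer. The lists share the same 6 libraries, which are ordered in this way over all genes, so their orders are not independent, and a single list is fully ordered in 10% of assignments by chance. The smallest exact permutation p was 0.1 (0.144 after Benjamini-Hochberg adjustment).

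**Figure D4:**
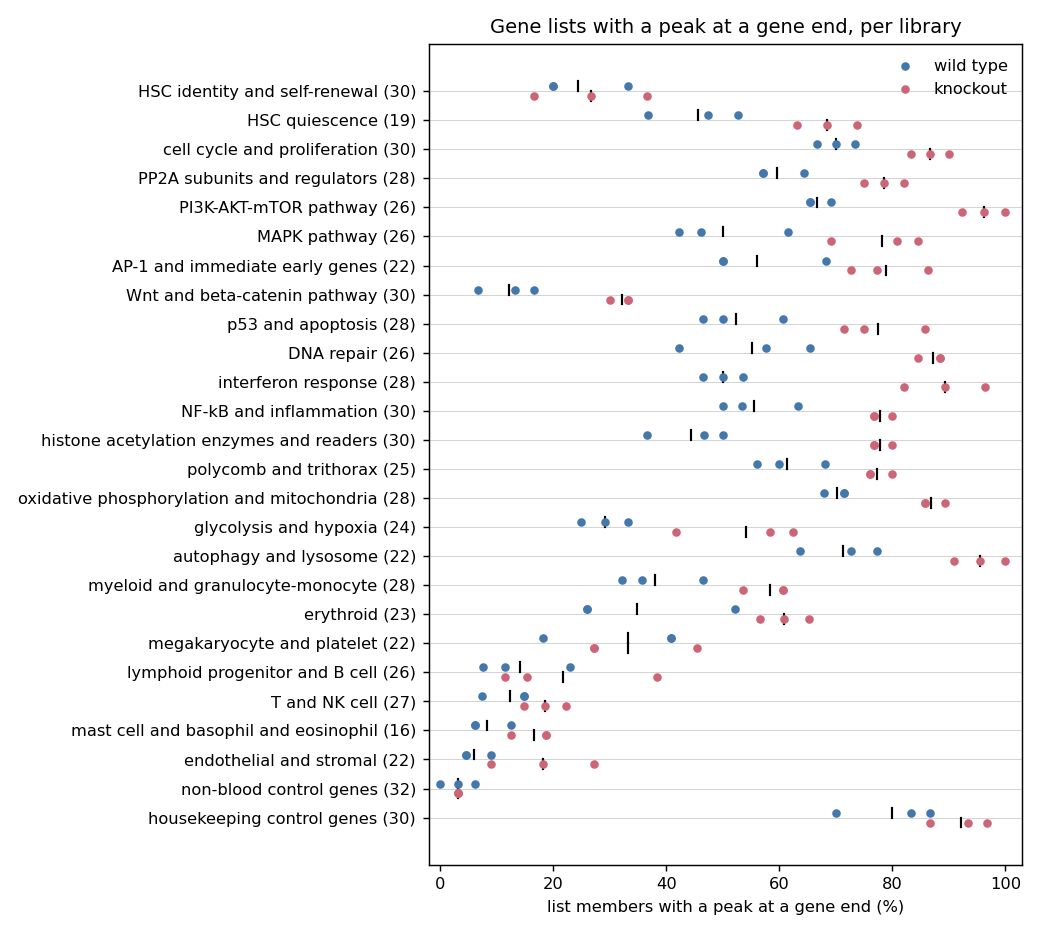
Percentage of each list's members (number in brackets) with a peak at a gene end, per library, with wild type in blue, knockout in red and the mean of 3 as a black tick. Interferon response genes lie at a mean of 25 members in the knockout against 14 in the wild type, and HSC identity genes at 8 against 7.33, all peaks counted.

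For no list did the share of knockout-only gene ends pass a test against the other marked genes. Fisher's exact test over 52 tests gave 0 lists with an adjusted p under 0.05 and 0 with an unadjusted p under 0.05. The histone acetylation list came closest, with 5 of 26 marked members knockout-only (odds ratio 2.71, exact p = 0.0545, adjusted p = 1), followed by the interferon list with 5 of 27 (odds ratio 2.59, exact p = 0.0626, adjusted p = 1). Random lists matched on rank in the knockout lists left 0 of 25 under an unadjusted p of 0.05.

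Regions whose nearest gene end, within 50 kb, belonged to a list were tested in the same way. Of the 193 regions near p53 and apoptosis genes, 14 (7.25%) were knockout-only, against a median of 2.79% in random lists (two-sided random-list permutation p = 0.0032, adjusted p = 0.13). Near interferon response genes 10 of 128 regions (7.81%) were knockout-only against 2.96% (permutation p = 0.0050, adjusted p = 0.13), and near endothelial and stromal genes 7 of 102 (6.86%) against 2.88% (permutation p = 0.0434, adjusted p = 0.752). These 3 were the only lists of the 52 tests under an unadjusted p of 0.05, and 0 passed the adjustment. Without wild-type replicate 1 the p53 list (20 regions, adjusted permutation p = 0.0208), the interferon list (13 regions, adjusted p = 0.0416) and, among wild-type-only regions, the myeloid list (3 regions, adjusted p = 0.0416) passed; over 11 settings each of these adjusted p-values reached up to 1.

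The last comparison asked whether peaks lay at gene ends more often in either genotype. A peak lay within 1000 bp of a protein-coding gene end for 26.4% ± 2.56 (SD, n = 3) of wild-type and 26.6% ± 4.30 (SD, n = 3) of knockout peaks, a difference smaller than the spread between libraries (two-sided exact permutation p = 1). Gene bodies were overlapped by 63.7% ± 1.95 and 70.1% ± 2.69 of peaks (SD, n = 3 each; exact permutation p = 0.1), but by 73.2% and 72.9% of those with a q-value of at most 0.05 (exact permutation p = 0.7). Among peaks with a q-value of at most 0.05 the gene-end share was 49.7% ± 0.482 in the wild type and 38.6% ± 3.33 in the knockout (SD, n = 3 each; exact permutation p = 0.1), while with equal numbers of peaks the knockout share was higher by 9.90 percentage points.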

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

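The threshold of a q-value of at most 0.05, the rank-matched lists and the leave-one-out runs of the gene lists were chosen after the data had been seen; the other settings were planned. The longer knockout lists, their coverage and the larger mean sharing within genotypes had the same direction in every setting run except the overlap of the shorter list, which gave -0.0145 for the sharing. The exact permutation test used cannot give a p under 0.1 at this sample size in any setting. Replicate numbers did not pair the libraries (correlations of 0.020, 0.0238 and -0.00994 for equal numbers), and the replicate block gave the same ratios of 1.62 and 2.36 with an exact sign-flip p of 0.25, its smallest, and the same gene-end difference of 0.203 points.

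Counts of exclusive sites depended on the threshold. Knockout-only regions numbered 1344 at a −log10 q-value of 5, 210 at 10, 4714 at a q-value of 0.05 and 1386 with equal lists. Wild-type-only regions numbered 2, 3, 2 and 66 in that order, 18 where peaks had to cover 50% of a region and 50 with summits clustered within 500 bp. Regions in all 6 libraries numbered 138, 67 and 1238 at those thresholds and 440 at 50% cover. Knockout-only genes numbered 1364, 227 and 2720 at the thresholds, and wild-type-only genes 0 at each and 6 with equal lists. Leaving out 1 library gave 3780 to 5641 knockout-only and 42 to 201 wild-type-only regions, and 1036 to 1563 and 4 to 13 genes, partly because fewer libraries then have to agree.

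The gene-end share, 0.203 points higher in the knockout, turned to -11.1 points at a q-value of 0.05, and lay between -1.29 and 2.67 without 1 library; the cause was not tested. For regions near gene lists, 2 lists (HSC quiescence and p53, adjusted permutation p = 0.0416 each) passed where 2 or 3 of 3 libraries sufficed, and 0 to 3 lists passed without 1 library; the adjusted p of each list ranged up to 1 over 11 settings. At gene ends 0 lists passed in any setting. The few fragments under a typical wild-type peak limit all statements of absence to this depth and enrichment.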

Other observations

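The tests of list length, depth, rank in the knockout lists and detection were chosen after the counts had been seen; those of other splits, of linkage to Ppp2ca and of rank-matched regions were set out before their results. Genes named in the next paragraph were chosen after their values were seen.

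Over the whole gene and with peaks of a q-value of at most 0.05, 10037 ± 807 protein-coding genes were marked in the knockout and 3219 ± 416 in the wild type (SD, n = 3 each), a ratio of 3.12 against which the lists below are to be read; none was tested against it. Of the 8374 genes marked in all 3 knockout libraries at this setting, 3353 (40.0%) had no wild-type peak and count as knockout-only. With all peaks over the same span, 0 cell cycle, HSC identity or housekeeping genes and 1 immediate early gene were knockout-only. That gene, Atf3, was not knockout-only at a q-value of at most 0.05. All knockout-only members named below thus had a wild-type peak above that q-value. Cell cycle genes were marked at 27 ± 1 of 30 members in the knockout and 9.33 ± 3.06 in the wild type (SD, n = 3 each). The 10 knockout-only members included the cyclins Ccna2, Ccnb2 and Ccnd2, the mitotic kinase Plk1, Mki67 and Top2a. HSC identity genes were marked at 15.3 ± 4.62 of 30 against 5.33 ± 0.577 members (SD, n = 3 each), with Hlf, Mllt3 and Prdm16 knockout-only and Erg, Etv6 and Runx1 marked in all 6 libraries. Immediate early genes were marked at 18.3 ± 2.08 of 22 against 4.33 ± 2.31 members (SD, n = 3 each), with Fos, Jun, Jund, Egr1 and Ier2 among 9 knockout-only members. The housekeeping control list was marked at 29.3 ± 1.15 of 30 against 14.3 ± 2.52 members (SD, n = 3 each), and 7 of its members, among them Actg1, Hprt and Pgk1, were knockout-only. Control genes of other organs had 0.333 marked members in the knockout and 0 in the wild type. In 25 of 26 lists every knockout library lay above every wild-type library, with an exact permutation p of 0.1 as the smallest possible.

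Knockout-only regions outnumbered the reverse, and several explanations were weighed. The count of 2824 was matched by 1 of 10 splits, the real one, with 503 as the highest of the others; for genes the counts were 898 and 90, again in 1 of 10 splits, and for the sharing within genotypes 0.0691 and 0.00773, in 1 of 10. These splits are too few for a share under 0.05. Longer knockout lists alone would leave similar numbers in both directions at equal length, provided that the cut lists held similar peaks. At equal length 1386 knockout-only regions stood against 66 wild-type-only ones and 317 in the highest other split. With all peaks, 100 shuffles that kept list lengths gave 679 to 830 knockout-only regions, and a simulation with each region at its own mean rate of detection and no group effect gave 1422, both below 2824. By contrast, with peaks of a q-value of at most 0.05 the shuffles gave 4192 to 4297 against 4714 observed, so at that threshold most of the count may follow from the lengths of the lists. Such peaks numbered 16120 to 23744 per knockout library and 3652 to 4695 per wild-type library. The wild-type lists thus held mostly weaker peaks, also when cut to 21917. Whether this difference in content gives the excess cannot be told from the equal lists, or from the shuffles and simulation with all peaks. Variants linked to the targeted locus do not account for the pattern, since 1.03% of knockout-only regions lay within 10 Mb of Ppp2ca.

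Deeper sequencing does not explain the larger number of stricter peaks in knockout replicate 2. It had the lowest background, 0.465, yet 16120 such peaks against 3652 to 4695 in the wild-type libraries. Per unit of background the lowest knockout library had 3.57 times as many as the highest wild-type library. That ratio takes peak numbers as proportional to depth. It cannot exclude a part of depth in knockout replicates 1 and 3, with the highest backgrounds of 0.738 and 0.827. The knockout-only regions as a whole were not a set of sites of ordinary strength without any mark in the wild type. The share of regions without a wild-type peak was 9.59 times as high in the weakest of 10 knockout rank groups as in the strongest 5. Such sites among them are not excluded, because weak regions are missed more often in any case. In the strongest 5 groups 5.14% of regions still had no wild-type peak. Detection in the wild-type libraries fell at 27 of 27 steps between neighbouring rank groups, over 3 libraries. That is consistent with lower enrichment over background in the wild-type libraries and equally with a higher level of the mark at most sites in the knockout. These cannot be told apart here, because library quality and genotype coincide and the labels name no spike-in.

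Regions near p53 and apoptosis genes and near interferon response genes were more often knockout-only than in random lists before adjustment. A candidate explanation is that these regions are weak in the knockout lists, where a wild-type peak is most easily missed. Matched on knockout rank, 14 p53 regions at 8 genes, among them Cdkn1a, Bax, Gadd45a and Pmaip1, stood against 9.35 expected (one-sided permutation p = 0.0493), and 10 interferon regions at 9 genes, among them Isg15, Xaf1 and Usp18, against 6.46 expected (one-sided permutation p = 0.0780). The first p lies within its Monte Carlo error of 0.00216 of the threshold, neighbouring regions of a gene are not independent, and 26 lists were matched in this way. The reading of both tests as open was settled after their values were seen; by the threshold of 0.05 set beforehand, the first would have counted against weak signal and the second for it. Neither list passed adjustment in the planned test (random-list permutation, adjusted p = 0.13 for both). Chance over many lists, weak signal and a specific gain near p53 and interferon genes therefore cannot be told apart. The endothelial and stromal list, also under 0.05 before adjustment, had 7 knockout-only regions against 4.72 expected after matching (one-sided permutation p = 0.152).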
